A study of Homo sapiens with 9 samples.

How the data were processed

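The deposited files hold m5C levels of HEK293T cells, a human embryonic kidney line, measured by bisulfite sequencing of RNA. Bisulfite turns unmethylated cytosine into uracil, so a cytosine that stays a cytosine in the reads is counted as methylated, whether it was methylated or escaped conversion. The 9 libraries form 3 groups of 3: NT, dCasRx-dNSUN6 and dCasRx-NSUN6. NSUN6 is an RNA m5C methyltransferase, and dNSUN6 is its catalytically inactive form, fused to the RNA-guided protein dCasRx. Per the labels, the RNA was poly(A)-selected after DNase treatment. The labels describe NT by a non-target guide and do not say which editor those cells received. The samples are not stated to be separate cultures, so p-values across libraries measure only the spread between these samples.

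There are 3 deposited tables, each comparing a pair of groups. The deposited unit of the library columns is a methylation fraction from 0 to 1 per site, per the file headers and the range of the values, and it is printed here as a percent. The p-value and q-value columns were made by the authors, with a test that is not given in the sources used here. The meth.diff column, also deposited by the authors, is the difference of methylation fractions, the first-named group minus the second. Its sign was checked against the replicate means at each site. Each table lists only sites with a p under 0.05 and an absolute difference of 0.05 or more. Sites that failed these limits are not in the files, so no share of all cytosines can be given; where a number of tested sites is used, it is inferred from the ratios of the deposited q and p values. The files used here hold no coverage: the depth behind each level is unknown, and no interval that needs it is given. Trimmomatic and the genome build hg38 are named per the submitters' processing notes; the aligner, the methylation caller and the coverage minimum are not given in the sources used here.

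Sites were placed in genes by the RefSeq gene table of GRCh38.p14, by gene bounds alone; strand and exons were not used. A site in a single protein-coding gene, or else in a single gene, took its name. A site in a 7SL RNA gene took that name even inside a longer gene, a rule added after the positions were seen. This gave 1 named gene for 20568, 19756 and 9807 sites of dCasRx-NSUN6 vs NT, dCasRx-NSUN6 vs dCasRx-dNSUN6 and dCasRx-dNSUN6 vs NT. A lone site is a site with no other listed site of the same table within 50 nt; a site with 4 or more such neighbours is called clustered. Both terms were chosen after the data were examined. Sites in a gene are not independent, since a read can span several of them.

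The counts of sites higher and lower were set against an even split with a two-sided exact binomial test over sites. Levels per library were transformed by the arcsine square root and retested with limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjustment over the listed sites of a table. These adjusted values are too small as a measure of all cytosines, since the sites were already selected for their difference. On simulated levels the retest recovered 14.0%, 16.0% and 22.0% of sites moved by 10 percentage points in the 3 tables. Of sites moved by 20 it recovered 56.0%, 57.0% and 57.0%. In each simulation 100 sites were moved by each size and all others had no difference. The levels were drawn from beta distributions with a precision fixed at 40, not taken from the data. The listed sites were selected for a difference, so these shares do not measure the power of the retest on them. Replicates of a pair of groups were called apart when all 3 of one lay above all 3 of the other, which chance gives at 10% of unselected sites. At the RPSA site, available in all 9 libraries, an exact two-sided permutation test compared the 3 dCasRx-NSUN6 libraries with the other 6. Permutation tests were also run over the mitochondrial sites listed in both dCasRx-NSUN6 tables. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used for all else.

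Within each table, 16 gene lists were tested by two-sided Fisher's exact tests of higher and lower sites against all other sites of the table, with Benjamini-Hochberg adjustment over the lists with 5 or more sites. The lists were cytosolic ribosomal proteins, translation initiation and elongation factors, m5C writers, erasers and readers, mitochondrially encoded genes, histone genes, chaperones and heat shock proteins, proteasome subunits, glycolysis enzymes, nuclear-encoded oxidative phosphorylation subunits, tubulins and actins, hnRNPs and SR splicing factors, aminoacyl-tRNA synthetases, cell cycle genes, interferon-stimulated and dsRNA-response genes, abundant non-coding RNAs, and amino acid stress and unfolded protein response genes. Lists were set by patterns of gene symbols. The translation factors therefore take in the kinases EEF2K, EIF2AK2 and EIF2AK4, the methyltransferases EEF1AKMT2 and EEF2KMT, EIF4EBP2 and the pseudogenes EEF1A1P6 and EEF1DP1. The proteasome list takes in PSME3, PSME4, PSMF1 and PSMG4, and the abundant non-coding RNAs leave out RN7SL3. The same test was used for annotation classes. Overlap between tables was counted by position and strand.

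The gene lists, the rule for named genes and the tests were chosen before the data were examined, with exceptions. The permutation tests were not planned, and the other exceptions are named where they occur. The rule took RPSA; in each table the 12 largest rises and 12 largest falls among sites with replicates apart, at most 1 per gene; up to 4 members per gene list; the 5 genes with most sites; and 5 sites listed in all 3 tables. Sites named outside this rule are said to be chosen after their values were seen. The alternatives set beforehand were differences of 0.10 and 0.20, a p under 0.01, the deposited q under 0.05, genes in place of sites, each replicate left out, replicate number as a block, limma on logit levels with an offset of 0.01, and overlap by gene. Left out were the sequence motif of NSUN6 and transcript regions, for want of a genome sequence and exons, and coverage minimums, for want of coverage. Without exons, position 234 of RPSA, named in the design, could not be placed on the genome.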

Results

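RNA m5C was measured in 9 bisulfite libraries of HEK293T cells, 3 each of NT, dCasRx-dNSUN6 and dCasRx-NSUN6, to ask whether an editor guided to the RPSA transcript also changes methylation elsewhere. Levels are percentages of reads with an unconverted cytosine, given as mean ± SD with n = 3 libraries per group, and positions are those of hg38. The depth behind the levels is unknown.

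RPSA encodes a protein of the small ribosomal subunit. Its lone listed site on chromosome 3, position 39408706, within the gene bounds 39406720 to 39412542, had a level of 78.5% ± 0.871 in dCasRx-NSUN6 (n = 3). The level was 70.0% ± 1.53 in NT and 70.3% ± 0.222 in dCasRx-dNSUN6 (n = 3 each). The 3 dCasRx-NSUN6 libraries, at 77.6% to 79.3%, all lay above the other 6, of which the highest reached 71.6%. The mean was higher by 8.53 percentage points than NT and by 8.21 than dCasRx-dNSUN6, while dCasRx-dNSUN6 and NT differed by 0.32. The exact two-sided permutation test of 3 against 6 libraries gave p = 0.0238 over 84 splits, the smallest it can give; 3 against 3 cannot go below 0.1. Only listed sites could be tested, which favours a small p. The planned limma retest did not call this site against NT or against dCasRx-dNSUN6 at a threshold of 0.05, with or without adjustment. Limma draws the spread of each site towards that of all listed sites, so this result does not rest on the site's own replicates alone. In the authors' deposited table q was 3.31e-74 against NT and 7.41e-67 against dCasRx-dNSUN6. Whether this site is the one named in the design could not be determined.

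A further 11 RPSA sites lay 119 nt or more away, at positions 39408825 to 39408853. Their mean was 43.4% ± 6.90 in dCasRx-NSUN6 and 19.6% ± 7.72 in NT, with replicates apart at all 11 and q under 0.05 at 6 in the authors' deposited table. At 8 of them dCasRx-dNSUN6 was listed too, at 40.04% ± 5.95 against 20.5% ± 9.20 in NT, with replicates apart at 6 and none with q under 0.05 in the authors' deposited table. None of the 11 was listed between dCasRx-NSUN6 and dCasRx-dNSUN6. Loci that resemble RPSA had lone sites with like levels. RPSA2 on chromosome 19, position 23827395, was at 82.2% ± 1.31 in dCasRx-NSUN6, 69.2% ± 1.28 in dCasRx-dNSUN6 and 69.5% ± 1.10 in NT. The pseudogenes RPSAP17 and RPSAP45 were at 86.0% ± 4.80 and 81.8% ± 5.89 in dCasRx-NSUN6, and at 75.2% ± 4.21 and 68.6% ± 5.61 in NT. In the authors' deposited table q for both was 0.766 against NT and 0.730 against dCasRx-dNSUN6. Reads of these loci may be shared with RPSA.

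**Figure D1:**
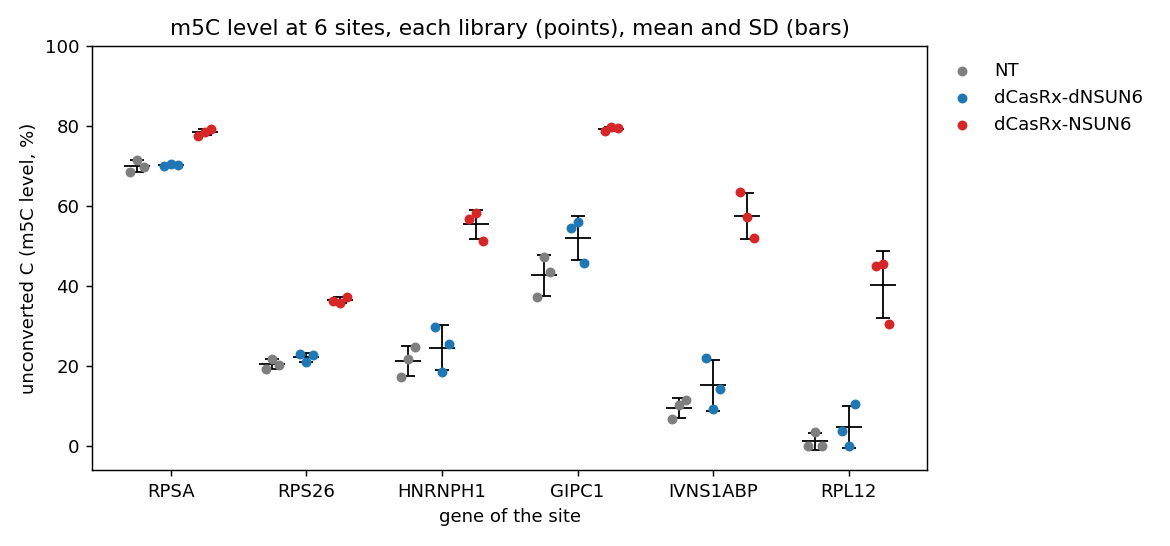
m5C level (unconverted C, %) at 6 sites, by gene, with 1 point per library and the mean ± SD as bars. At each of these sites the 3 dCasRx-NSUN6 libraries lie above the other 6, at RPSA with means of 78.5% against 70.0% and 70.3%; apart from RPSA, RPL12, HNRNPH1 and IVNS1ABP, the sites were chosen after their values were seen.

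The comparison of dCasRx-NSUN6 with NT asks what changes when active NSUN6 with the RPSA guide is set against the non-target condition. Sites in genes unrelated to RPSA had differences far larger than that at RPSA. IVNS1ABP, on chromosome 1 at position 185305672, was at 57.6% ± 5.76 against 9.55% ± 2.43 in NT. F11R, which encodes a tight junction adhesion protein, was at 83.4% ± 9.08 against 37.1% ± 10.5. PTPN13, a tyrosine phosphatase, was at 70.5% ± 4.54 against 27.3% ± 6.76. CYBA, a subunit of NADPH oxidase, was at 84.8% ± 13.2 against 37.8% ± 16.8, and the receptor gene FGFR4 at 74.7% ± 12.9 against 26.8% ± 10.6. TMEM138 was at 93.7% ± 3.31 against 53.4% ± 11.5, GANAB, a subunit of glucosidase II, at 59.9% ± 9.04 against 19.7% ± 12.1, and ZNF629 at 50.7% ± 1.25 against 10.4% ± 14.3. These 8 sites are lone, with a q under 0.05 in the authors' deposited table. Replicates apart was a condition of their choice. Others of the 12 largest rises, in LUC7L, PKP4 and CKLF, had q of 0.0735, 0.102 and 0.244 there.

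The largest differences in the other direction were within mitochondrial genes. MT-ND4 at position 10933 was at 14.7% ± 13.5 in dCasRx-NSUN6 and 59.5% ± 16.0 in NT, and MT-ATP8 at position 8485 was at 0.900% ± 1.56 against 36.5% ± 13.7. MT-ATP6 at position 8573 was at 2.27% ± 3.94 against 39.9% ± 18.2, and MT-COX3 at position 9591 at 9.13% ± 8.36 against 43.0% ± 13.7. The last 3 sites lie on the minus strand, opposite to these genes. Among nuclear genes, COL18A1, a collagen gene, was at 16.6% ± 6.85 against 55.2% ± 14.5. CHTF18, which acts in sister chromatid cohesion, was at 43.0% ± 5.39 against 73.1% ± 5.58, and SLIT2, a guidance cue of axons, at 41.5% ± 16.2 against 69.6% ± 5.36. In the authors' deposited table q was 0.0115 for CHTF18, but 0.233 for COL18A1 and 0.157 for SLIT2.

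In all, 22447 sites in 4020 named genes were listed for dCasRx-NSUN6 vs NT, of which 18278 were higher and 4169 lower in dCasRx-NSUN6. The higher share was 81.4% (exact 95% interval 80.9% to 81.9%, over sites, which are not independent), with a two-sided exact binomial p at the floor of 1e-300. The median difference of the higher sites was 9.16 percentage points and that of the lower sites -7.55, by the authors' deposited table. Replicates were apart at 8612 higher and 1288 lower sites, together 44.1%, where chance gives 10% of unselected sites. In the authors' deposited table q was under 0.05 at 1089 sites, 939 higher and 150 lower. Of the 963 nuclear sites among them 937 were higher, and of the 126 mitochondrial sites 124 were lower.

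The retest across replicates called 0 sites by limma at an adjusted p under 0.05; the smallest adjusted p was 0.0522, and 8687 sites had an unadjusted p under 0.05. With limma on logit levels it called 2871, of which 2538 were higher. With a dCasRx-NSUN6 library left out it called 2655 (replicate 1), 3280 (replicate 2) and 2995 (replicate 3), so the count depends on these libraries and on the scale.

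Most listed sites were close to others. The 11567 clustered sites, with 4 or more listed neighbours within 50 nt, were higher at 10107 and lower at 1460. Over them the dCasRx-NSUN6 libraries averaged 23.2%, 16.0% and 16.5% for replicates 1, 2 and 3, and NT 9.00%, 9.90% and 10.5%. By the number of listed sites the first genes were LUC7L, related to the U1 splicing factors, with 102, OGA, which removes O-GlcNAc from proteins, with 91, the nuclear export receptor XPO1 with 87, and MDM4, an inhibitor of p53, and TAF15, each with 86. Their sites averaged 18.2% ± 5.26 against 7.65% ± 0.818 in LUC7L, 14.6% ± 3.17 against 4.93% ± 0.609 in OGA, 14.5% ± 2.64 against 4.196% ± 0.979 in XPO1, 37.1% ± 1.66 against 23.9% ± 4.32 in MDM4 and 13.3% ± 5.41 against 5.96% ± 1.25 in TAF15. In LUC7L replicate 1 stood apart at 24.2%, against 16.0% and 14.4% in replicates 2 and 3. In the authors' deposited table q was under 0.05 at 0 of the LUC7L and TAF15 sites, 5 in OGA, 4 in MDM4 and 2 in XPO1.

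Lone sites numbered 4587, of which 3258 were higher and 1329 lower. With q under 0.05 in the authors' deposited table there were 235, 228 of them higher, and replicates were apart at 97.4% of the 235. At the 228 the dCasRx-NSUN6 libraries averaged 33.2%, 32.1% and 33.2%, and NT 15.3%, 17.3% and 17.0%. These sites were selected by q from the same libraries, which favours such separation and such a gap. Sites in abundant housekeeping mRNAs, chosen after their values were seen, had small spreads. RPS26, a ribosomal protein gene, was at 36.5% ± 0.795 against 20.5% ± 1.24 in NT, and RPS3 at 34.6% ± 1.03 against 27.9% ± 0.890. The actin genes ACTG1 and ACTB were at 21.5% ± 0.593 against 12.5% ± 0.401 and at 8.22% ± 0.340 against 3.02% ± 0.0361. HSPD1, a mitochondrial chaperonin, was at 11.8% ± 0.917 against 4.31% ± 0.896, and COX5A, a subunit of cytochrome c oxidase, at 25.5% ± 1.95 against 12.7% ± 1.67.

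**Figure D2:**
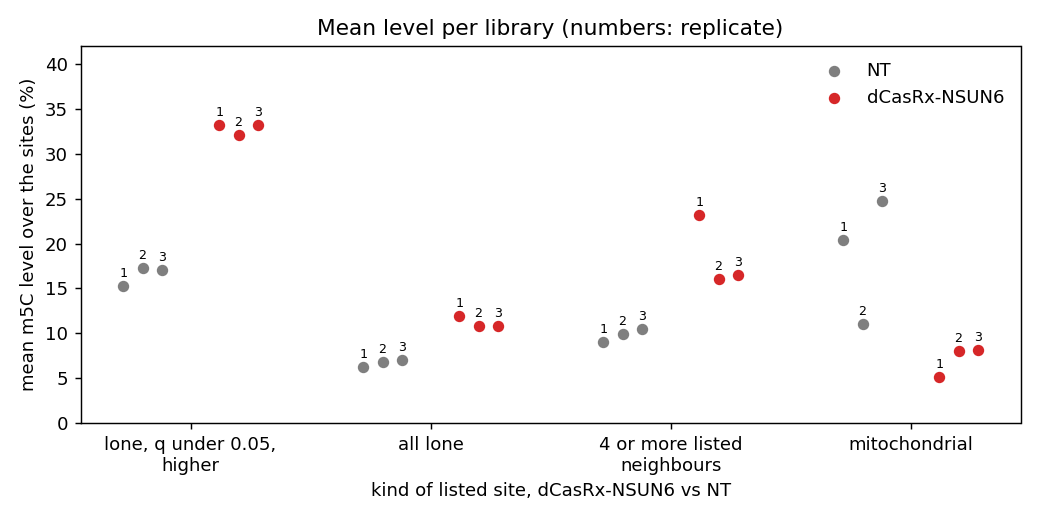
Mean m5C level (%) of each library over 4 kinds of sites listed for dCasRx-NSUN6 vs NT, with points numbered by replicate. Over lone sites with q under 0.05 and higher levels the dCasRx-NSUN6 libraries sit at 33.2%, 32.1% and 33.2%, while over clustered sites replicate 1, at 23.2%, sits above replicates 2 and 3.

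Of the gene lists, 3 passed the test against the other sites of this table. Mitochondrially encoded genes had 14 higher and 214 lower sites in 11 genes (6.14% higher, against 82.2% of all others, adjusted Fisher's exact p = 3.01e-137). Proteasome subunits had 74 higher sites and 1 lower in 14 genes (98.7% higher, adjusted Fisher's exact p = 6.09e-05); PSMB2 was at 71.7% ± 11.0 against 47.1% ± 13.4 in NT and PSMA5 at 17.9% ± 6.23 against 0%, with q of 0.0628 and 0.766 in the authors' deposited table. Histone genes had 45 higher and 1 lower in 7 genes (97.8% higher, adjusted Fisher's exact p = 0.00959); H2AZ2, a histone variant gene, was at 26.3% ± 11.6 against 3.61% ± 4.27 and H3-3B at 54.2% ± 4.72 against 36.7% ± 7.72. In H1-10, a linker histone gene, all 14 listed sites were higher, at 65.7% ± 9.16 against 54.5% ± 4.06, with replicate 1 at 76.0% and replicates 2 and 3 at 62.7% and 58.4%. With genes in place of sites the adjusted p was 0.360 for proteasome subunits (14 genes higher, 0 lower) and 1.00 for histone genes, and at a difference of 0.10 or more it was 0.148 for histone genes.

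The other 13 lists did not pass, the smallest adjusted Fisher's exact p being 0.133, for the abundant non-coding RNAs. Cytosolic ribosomal proteins had 331 higher and 73 lower sites in 44 genes, among them RPL12 at 40.3% ± 8.43 against 1.19% ± 2.06 and RPL22 at 43.2% ± 10.4 against 8.20% ± 2.52. Translation initiation and elongation factors had 167 higher and 33 lower, some of them in the kinase genes EIF2AK2 and EEF2K, with the release factor gene ETF1 at 58.4% ± 10.8 against 33.0% ± 6.84. The hnRNPs and SR splicing factors had 193 higher and 32 lower, with HNRNPH1 at 55.5% ± 3.63 against 21.3% ± 3.82 and HNRNPLL at 62.0% ± 10.5 against 16.9% ± 16.9. Abundant non-coding RNAs had 58 higher and 5 lower, with SNHG1 at 47.1% ± 4.54 against 18.7% ± 8.36, and aminoacyl-tRNA synthetases 42 higher and 6 lower, with QARS1 at 73.2% ± 3.19 against 57.3% ± 2.39. Chaperones and heat shock proteins had 105 higher and 22 lower, nuclear-encoded oxidative phosphorylation subunits 66 and 9, cell cycle genes 53 and 8, glycolysis enzymes 18 and 2, amino acid stress and unfolded protein response genes 18 and 7, interferon-stimulated and dsRNA-response genes 10 and 6, and m5C writers, erasers and readers 8 and 4. Tubulins and actins had 13 higher sites and 0 lower, some of them in TUBGCP2 and TUBGCP4, which belong to the gamma-tubulin complex.

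By annotation, 88.2% of the sites lay in protein-coding genes, 81.0% of them higher. Sites in lncRNA genes were higher at 412 and lower at 51 (89.0% higher, adjusted Fisher's exact p = 1.90e-05), and sites in no gene at 915 and 133 (87.3% higher, adjusted Fisher's exact p = 5.49e-07). For the lncRNA genes the share was 81.1% against dCasRx-dNSUN6 (adjusted Fisher's exact p = 0.302) and 69.8% in dCasRx-dNSUN6 vs NT (adjusted Fisher's exact p = 8.44e-05, but 0.574 at a difference of 0.10 or more).

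The comparison of dCasRx-NSUN6 with dCasRx-dNSUN6 sets the active against the inactive enzyme. IVNS1ABP was at 57.6% ± 5.76 against 15.2% ± 6.43 in dCasRx-dNSUN6, and PTPN13 at 70.5% ± 4.54 against 27.2% ± 11.6. DEPDC1 was at 67.4% ± 12.3 against 12.2% ± 7.71, and APTX, which repairs DNA ends, at 55.4% ± 8.47 against 8.99% ± 3.58. XPOT, the export receptor of tRNA, was at 49.7% ± 15.3 against 7.12% ± 6.60, and MDM4 at position 204555228 at 83.0% ± 5.88 against 41.5% ± 25.4. Lower levels were found in GNA13, a G protein subunit, at 6.95% ± 5.23 against 43.4% ± 5.96, in SLC35C1, a GDP-fucose transporter, at 28.8% ± 2.95 against 70.9% ± 21.5, and in ATL2, which shapes the endoplasmic reticulum, at 12.6% ± 8.47 against 45.3% ± 11.9. Of these sites, those of SLC35C1 and ATL2 had q of 0.205 and 0.150 in the authors' deposited table, and the others q under 0.05. Others of the 12 largest rises, in CYBA, GANAB and VPS9D1, had q of 0.186, 0.116 and 0.130 there. The MDM4 site was listed in dCasRx-dNSUN6 vs NT too, with a difference of -20.36 percentage points. In dCasRx-NSUN6 vs NT its difference was 29.65, with a q of 0.216 in the authors' deposited table.

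The table listed 21473 sites in 4062 named genes, 16915 higher and 4558 lower in dCasRx-NSUN6 (78.8% higher, exact 95% interval 78.2% to 79.3%, exact binomial p at the floor of 1e-300). Replicates were apart at 7748 higher and 1262 lower sites, where chance gives 10% of unselected sites. In the authors' deposited table q was under 0.05 at 674 sites, 611 higher and 63 lower; lone sites with q under 0.05 numbered 154, of which 150 were higher. By the number of sites the first genes were OGA with 104, VHL, the von Hippel-Lindau tumour suppressor gene, with 92, MDM4 with 82, RPS10 with 80 and TAF15 with 79. In VHL the sites averaged 28.1% in dCasRx-NSUN6 replicate 1, against 12.96% and 11.8% in replicates 2 and 3 and 8.84% ± 0.649 in dCasRx-dNSUN6. The retest by limma called 0 sites, with 7768 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0599, while limma on logit levels called 2500, of which 2203 were higher. Without dCasRx-NSUN6 replicates 1, 2 and 3 in turn limma called 2416, 3363 and 3084.

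Against dCasRx-dNSUN6 the same 3 lists passed. Mitochondrially encoded genes had 26 higher and 146 lower sites (adjusted Fisher's exact p = 1.51e-70), proteasome subunits 94 and 6 (adjusted Fisher's exact p = 0.000320) and histone genes 43 and 2 (adjusted Fisher's exact p = 0.0161). With genes in place of sites the adjusted p was 0.782 for proteasome subunits and 1.00 for histone genes. The cytosolic ribosomal proteins, with 321 higher and 63 lower, had an adjusted Fisher's exact p of 0.0535. At a difference of 0.10 or more it was 0.0429 for these (89.9% higher), for cell cycle genes (24 higher, 0 lower) and for translation initiation and elongation factors (75.9% higher, below the other sites). It was 0.00705 there for chaperones and heat shock proteins (60 higher, 2 lower) and for abundant non-coding RNAs (6 higher, 7 lower). RPS10 at position 34422842 was at 67.8% ± 21.1 against 29.1% ± 10.3. The same site was listed in dCasRx-dNSUN6 vs NT too, with a difference of -24.95 percentage points. SRSF10, a splicing factor gene, was at 35.3% ± 12.9 against 4.55% ± 5.41, and NSUN2, another m5C methyltransferase gene, at 50.7% ± 7.67 against 26.2% ± 22.7, the latter with a q of 0.838 in the authors' deposited table.

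**Figure D3:**
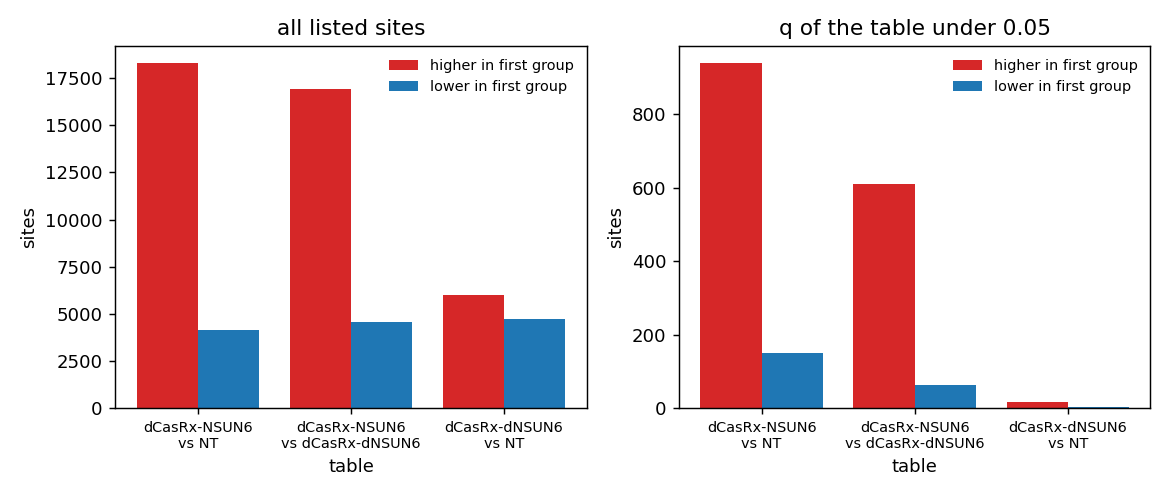
Number of sites higher (red) and lower (blue) in the first-named group in each table, for all listed sites and for those with q under 0.05. dCasRx-NSUN6 vs NT has 939 higher and 150 lower sites with q under 0.05, and dCasRx-dNSUN6 vs NT has 16 and 5.

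The comparison of dCasRx-dNSUN6 with NT sets the inactive editor against the non-target condition, for which the editor is not stated. AMD1, which encodes an enzyme of polyamine synthesis, was at 55.6% ± 22.2 against 5.71% ± 5.15 in NT, and MSI1, an RNA-binding protein gene, at 48.7% ± 4.71 against 18.6% ± 8.49. GCN1, which acts in the response to amino acid shortage, was at 60.2% ± 10.3 against 21.7% ± 11.7. Lower levels were found in GNE, an enzyme of sialic acid synthesis, at 20.1% ± 8.86 against 47.0% ± 14.3, in PPP1R13L at 31.8% ± 1.36 against 63.1% ± 8.97, and within MT-COX3, on the opposite strand, at position 9565 at 38.0% ± 8.33 against 67.1% ± 8.35. AMD1 had a q of 0.146 in the authors' deposited table, and the other 5 sites a q of 1.00.

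For dCasRx-dNSUN6 vs NT 10760 sites in 2952 named genes were listed, 6007 higher and 4753 lower in dCasRx-dNSUN6 (55.8% higher, exact 95% interval 54.9% to 56.8%, two-sided exact binomial p = 1.15e-33 over sites). Replicates were apart at 2139 higher and 1521 lower sites, where chance gives 10% of unselected sites. In the authors' deposited table q was under 0.05 at 21 sites, 16 higher and 5 lower, and replicates were apart at 2 of the 21. Of these, 14 lay in genes of 7SL RNA, the RNA of the signal recognition particle: 7 in RN7SL1 and 7 in RN7SL2, all higher. Over the 7 sites of RN7SL1 the dCasRx-dNSUN6 libraries were at 18.05%, 29.8% and 24.3% and NT at 14.5%, 21.1% and 15.6%. Over those of RN7SL2 they were at 23.6%, 39.2% and 29.4%, and NT at 14.7%, 26.9% and 16.8%. The copies of 7SL are nearly identical, so reads may be shared. A site in the NSUN6 gene itself, at position 18545937 of chromosome 10, was at 9.38%, 16.7% and 3.81% in dCasRx-dNSUN6, at 0.170%, 12% and 0.110% in NT and at 0% in dCasRx-NSUN6. The rest were 3 sites in MT-ND6, 1 in ZCCHC14 (100% against 79.3% ± 12.3) and 2 outside genes on chromosome 5.

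The retest by limma called 0 sites of dCasRx-dNSUN6 vs NT, with 3256 at an unadjusted p under 0.05, and limma on logit levels called 1080, 570 higher and 510 lower. Without a library limma called 1207, 1279 and 998 (dCasRx-dNSUN6 replicates 1, 2 and 3) and 1113, 1050 and 927 (NT replicates 1, 2 and 3). The direction turned with the group that lost a library: 862, 901 and 704 of the first 3 sets were higher, but 407, 341 and 353 of the last 3. Of the gene lists, 3 passed. Mitochondrially encoded genes had 11 higher and 171 lower sites (adjusted Fisher's exact p = 1.62e-46 over sites, which are not independent), with replicates apart at 14 of the 171. Over all mitochondrial sites of this table NT stood at 30.4%, 15.7% and 31.2% and dCasRx-dNSUN6 at 18.7%, 19.6% and 13.9%, so the groups overlap at NT replicate 2. Abundant non-coding RNAs had 34 higher and 6 lower (adjusted Fisher's exact p = 0.00127), 10 of the higher ones in RN7SL1 and 9 in RN7SL2; the adjusted p was 0.524 with genes in place of sites and 0.807 at a difference of 0.10 or more. Interferon-stimulated and dsRNA-response genes had 1 higher and 11 lower sites in 3 genes (adjusted Fisher's exact p = 0.00473), too few genes for a test by gene, and at a difference of 0.10 or more the adjusted p was 0.0544. STAT2, a transcription factor of interferon signalling, was at 2.90% ± 5.02 against 17.8% ± 6.61, with a q of 1.00 in the authors' deposited table. Genes with most sites were MT-ATP6 with 53, none higher, LUC7L with 46, MDM4 with 41, MT-ND4 with 40 and FDPS, an enzyme of the mevalonate pathway, with 33. Of these, 38 were higher in LUC7L, 25 in MDM4, 0 in MT-ND4 and 21 in FDPS. The LUC7L sites averaged 13.7% ± 1.33 in dCasRx-dNSUN6 against 6.20% ± 0.926 in NT, so they were mostly higher with the inactive enzyme too.

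Most listed sites within mitochondrial genes were lower in dCasRx-NSUN6 than in either other group. At the 157 mitochondrial sites listed in both dCasRx-NSUN6 tables the mean was 6.23% ± 1.92 in dCasRx-NSUN6, 15.2% ± 2.83 in dCasRx-dNSUN6 and 20.6% ± 7.86 in NT, where replicate 2 stood at 11.8% against 23.1% and 26.9%. The permutation test of the 3 dCasRx-NSUN6 libraries against the other 6 gave p = 0.0238 over these sites. A permutation test of dCasRx-dNSUN6 against NT gave p = 0.4. These sites were selected by the differences of dCasRx-NSUN6, which favours a small p in the former, so no conclusion is drawn from it. The 61 sites within MT-ATP6, a subunit of ATP synthase, averaged 3.28% ± 1.68, 13.7% ± 4.27 and 20.1% ± 8.57 in dCasRx-NSUN6, dCasRx-dNSUN6 and NT. The 40 sites within MT-COX2, a subunit of cytochrome c oxidase, averaged 4.49% ± 1.63, 13.4% ± 3.39 and 17.3% ± 6.82 in the same order. Of these, 48 of the 61 and all 40 lay on the minus strand, opposite to both genes, so the levels may not be those of their mRNAs. Other genes differed: the 4 sites of MT-COX1 listed against NT were all higher (45.0% ± 8.48 against 28.2% ± 2.32). Against dCasRx-dNSUN6 12 of 16 sites of MT-ND4L and 13 of 30 of MT-ND4 were higher. All mitochondrial sites taken, 14 of 231 were higher against NT (6.06%, adjusted Fisher's exact p = 6.39e-140 against nuclear sites), 26 of 175 against dCasRx-dNSUN6 (14.9%), and 11 of 188 in dCasRx-dNSUN6 vs NT (5.85%). A site of the 12S ribosomal RNA gene MT-RNR1, chosen after its values were seen, went the other way, with 77.5% ± 1.04 in dCasRx-NSUN6, 68.7% ± 1.18 in dCasRx-dNSUN6 and 66.2% ± 1.30 in NT.

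**Figure D4:**
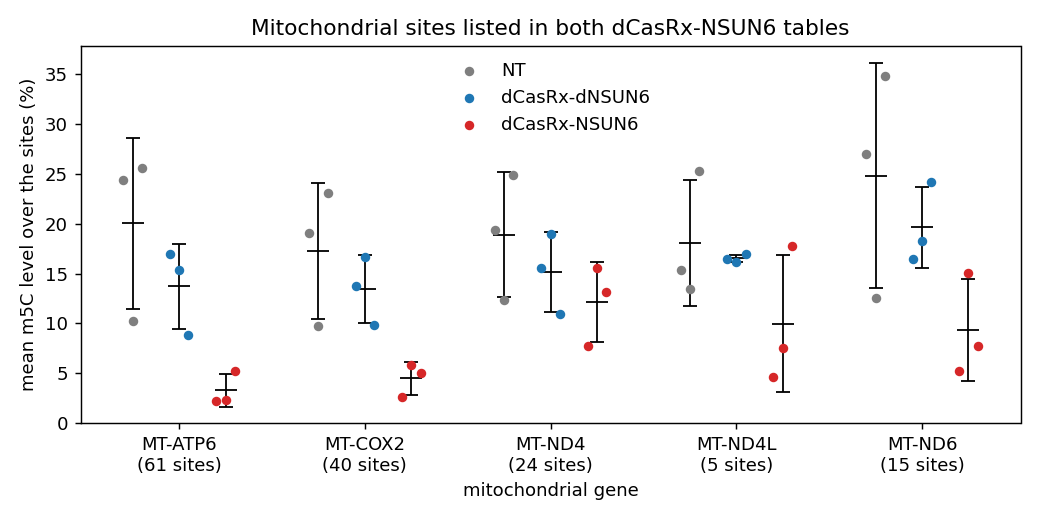
Mean m5C level (%) over the sites within 5 mitochondrial genes listed in both dCasRx-NSUN6 tables, with 1 point per library and mean ± SD as bars. In MT-ATP6 (61 sites) the 3 dCasRx-NSUN6 libraries, with a mean of 3.28%, lie below the other 6.

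The 2 tables that share the dCasRx-NSUN6 libraries had 8213 sites in common, 7559 higher and 641 lower in both, and 13 with opposite directions. If all 4955467 sites that the q values imply for the second table were tested in both, independent lists would share about 62.4 and 3.83 in the same directions; the number tested in both is unknown. Shared libraries alone raise such an overlap, by an amount that could not be computed from the listed sites. The tables that share NT had 3195 sites in common, and those that share dCasRx-dNSUN6 had 2838. At 2812 of the 8213 sites all 3 dCasRx-NSUN6 libraries lay above the other 6, and at 219 below; chance gives 1.19% of unselected sites in each direction. With q under 0.05 in both of the authors' deposited tables, 113 lone sites in 108 named genes were higher and 1 was lower. At 112 of the 113 the 3 dCasRx-NSUN6 libraries lay above the other 6. Means over the sites were 37.8% ± 0.848 in dCasRx-NSUN6, 21.1% ± 1.33 in dCasRx-dNSUN6 and 20.1% ± 1.49 in NT. These 113 sites were selected by their differences in the same 9 libraries, which favours such separation and such a gap. They include RPL12 (4.79% ± 5.33 in dCasRx-dNSUN6), HNRNPH1 (24.6% ± 5.66), F11R (49.7% ± 8.25) and TMEM138 (59.4% ± 20.6). Among sites with neighbours, 262 were higher with q under 0.05 in both, and at 150 of these (57.3%) all 3 dCasRx-NSUN6 libraries lay above the other 6. Of all sites, 310 were listed in all 3 tables, among them MDM4 position 204555237, at 91.8% ± 2.59 in dCasRx-NSUN6, 51.2% ± 29.1 in dCasRx-dNSUN6 and 69.2% ± 20.9 in NT.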

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

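The alternative of counting lone sites, the windows of 25 and 100 nt, and the library left out at the RPSA site and for replicates apart were chosen after the data were seen; all other alternatives here were set beforehand. The higher and lower split of listed sites kept its direction under each alternative run: with a library left out it was 78.9% to 84.5% higher (dCasRx-NSUN6 vs NT), 75.3% to 81.9% (dCasRx-NSUN6 vs dCasRx-dNSUN6) and 52.7% to 60.6% (dCasRx-dNSUN6 vs NT). Naming the tables in that order, a difference of 0.10 or more left 9330, 8487 and 3323 sites, 0.20 or more 1667, 1378 and 348, a p under 0.01 10484, 9359 and 3291, and a q under 0.05 1089, 674 and 21, in the authors' deposited tables; lone sites numbered 4587, 4653 and 3103, and genes in place of sites 4020, 4062 and 2952. These are smaller by construction. With a library left out, 16930 to 20430, 15908 to 19179 and 8756 to 9240 sites kept a difference past 0.05.

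The retest called 0 sites in each table by limma and 2871, 2500 and 1080 on logit levels. With a library left out it called 0 to 3280, 0 to 3363 and 927 to 1279; among the runs that called any, the lowest were 2655 and 2416 in the first and second table, without dCasRx-NSUN6 replicate 1, and no call was made there without a control library. In the third table most calls were higher without a dCasRx-dNSUN6 library (862 of 1207, 901 of 1279 and 704 of 998) and lower without an NT library (706 of 1113, 709 of 1050 and 574 of 927). The cause was not tested; the smallest adjusted p of 0.0522, 0.0599 and 0.0926 lay near the threshold. With replicate number as a block limma called 0 in each table. Deviations from the group mean correlated across sites by -0.0906, -0.0137 and -0.0700 between libraries of the same number in the first table. The values were -0.0731, 0.00891 and 0.00408 in the second and 0.0761, 0.0155 and 0.0363 in the third. Between different numbers those of the third ran from -0.0508 to 0.0114. The sites were selected for a group difference, so these values cannot settle whether the numbers pair the samples. Of 10 splits of the 6 libraries, 10, 10 and 10 called as many sites as the real one, which called 0. The highest of the others called 0, 0 and 2. Every split calls at least 0 sites, so this comparison cannot set the real groups apart, and no conclusion is drawn. With 10 splits the share could in any case not go under 0.1.

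Of the gene lists, 1, 1 and 1 passed with genes in place of sites, in each table the mitochondrially encoded genes, where fewer units are tested. At a difference of 0.10 or more 8 passed in dCasRx-NSUN6 vs dCasRx-dNSUN6 and 1 in dCasRx-dNSUN6 vs NT; the cause was not tested. Shared sites at 0.10 or more numbered 3639 (both dCasRx-NSUN6 tables), 936 (NT shared) and 737 (dCasRx-dNSUN6 shared), and 2907 genes were shared by both dCasRx-NSUN6 tables. Among single lists and annotation classes, 14 alternatives ended a call and 7 added a call. Some turned a direction: abundant non-coding RNAs against dCasRx-dNSUN6 went from 48 higher and 22 lower to 6 and 7 at 0.10 or more, and other non-coding genes there from 45.0% to 66.7% higher. Interferon-stimulated and dsRNA-response genes against NT went from 10 and 6 to 2 and 3, and by gene 15 and 18 ribosomal proteins were higher and lower in dCasRx-dNSUN6 vs NT, from 85 and 75 sites. Coverage minimums of 20 and 50 reads, a beta-binomial test, the sequence motif and transcript regions were not run. Without coverage, differences at sites with few reads cannot be told from counting noise.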

Other observations

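At clustered sites, tests chosen only after the result was seen were those of replicate 1 alone and of the active enzyme. At lone sites they were those of lower conversion, of the motif and of the active enzyme. The test of the p values of dCasRx-dNSUN6 vs NT was also chosen then, and the permutation tests were outside the plan. Genes named next were likewise chosen after their values were seen. Further lone sites were higher in dCasRx-NSUN6 than in both other groups. WDR77, a partner of the arginine methyltransferase PRMT5, was at 43.0% ± 0.880 against 22.2% ± 3.18 in dCasRx-dNSUN6 and 18.9% ± 2.17 in NT. STUB1, a ubiquitin ligase that works with chaperones, was at 26.6% ± 1.27 against 14.03% ± 0.540 and 12.5% ± 1.68. CCT5, a subunit of the chaperonin TRiC, was at 33.1% ± 1.73 against 20.3% ± 0.907 and 18.9% ± 1.25. SF3B3, a splicing factor subunit, was at 17.6% ± 1.16 against 7.16% ± 2.18 and 6.27% ± 0.879, and SRSF4 at 24.1% ± 2.40 against 12.5% ± 2.14 and 10.4% ± 0.665. A second site of HNRNPH1, at position 179616893, was at 40.7% ± 1.59 against 27.3% ± 1.30 and 27.7% ± 2.30.

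Listed sites of RN7SL1 and RN7SL3 were higher in the first-named group in all 3 tables, and those of RN7SL2 only in the tables against NT. For RN7SL1 only dCasRx-dNSUN6 vs NT had sites with q under 0.05 in the authors' deposited table. Its 8 sites in dCasRx-NSUN6 vs NT had a smallest q of 0.224 there. Against dCasRx-dNSUN6 it had 1 site, with a q of 0.730 and replicates that overlapped. RN7SL3 had 6 sites, higher in dCasRx-NSUN6 than in NT, where replicate 1 stood at 21.9% and replicates 2 and 3 at 4.03% and 10.4%, against 4.25% ± 0.955. RN7SL2 had 7 sites, lower in dCasRx-NSUN6 than in dCasRx-dNSUN6, at 22.6% ± 5.01 against 30.7% ± 7.87. A pair of adjacent sites outside genes on chromosome 5, positions 71850916 and 71850917, spread within groups: NT stood at 25.3%, 97.0% and 98.7% and dCasRx-dNSUN6 at 13.2%, 98.8% and 77.4%.

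Lone sites with q under 0.05 that were higher in dCasRx-NSUN6 than in NT numbered 228. Replicate 1 alone is argued against, since replicates 2 and 3 lay above all NT libraries at 97.8% of them. Lower conversion throughout the dCasRx-NSUN6 libraries would raise mitochondrial sites too, but 6.06% of the 231 listed were higher. This argues against it only for these sites, which are a limited check. Of them 225 had listed neighbours, 157 of the 217 lower ones lay on the minus strand, and the 2 in MT-RNR1 were higher. Conversion that differs by RNA stays open. Active NSUN6 is consistent with the 1 such site in dCasRx-dNSUN6 vs NT, but the editor in NT is not stated, and a difference in handling between the groups was not tested and stays open. The q values fall into 3 sets that may follow sequence context. If so, a C followed by TCCA would lie in the largest, which held 36.6% of the sites, and this argues against that motif at most of them. The largest set held 59.4% of the sites that the q values imply were tested. The smallest set held 12.7% of those, but 27.2% of the lone higher sites. Against dCasRx-dNSUN6 the shares of the smallest set were 12.4% and 36.3%. At higher sites with q under 0.05 and listed neighbours it held 22.1% against NT and 24.4% against dCasRx-dNSUN6. The excess was thus not limited to lone sites. The cause of this excess was not tested.

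Clustered sites, also mostly higher in dCasRx-NSUN6, differed more between its replicates. Stretches of unconverted reads are consistent with the data: deviations of replicate 1 from replicates 2 and 3 at neighbouring sites correlated by 0.859 over 10061 pairs of sites, which are not independent, against 0.0200 after shuffling, and those of NT by 0.824. Replicate 1 alone cannot be told apart from the rest: the median difference from NT was 7.82 percentage points in replicates 2 and 3, but 8.79 to 10.6 in pairs of replicates at such sites of dCasRx-dNSUN6 vs NT, so the listing limits give such a value. Activity of NSUN6 on neighbouring cytosines cannot be told apart from the rest, because 46.3% of these sites were also higher against dCasRx-dNSUN6 and the same dCasRx-NSUN6 libraries enter both tables. Reads left unconverted by RNA structure or by methylation look alike without the reads themselves.

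Of the 21 sites with q under 0.05 in the authors' deposited table of dCasRx-dNSUN6 vs NT, the replicates of the groups overlapped at 19. This is consistent with p values that count reads and not replicates. Whether the 7SL sites among them reflect a change in these cells was not tested further.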
